A study of Mus musculus with 2 samples.

How the data were processed

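NIH3T3 cells, an established mouse embryonic fibroblast line, were measured on 2 single-colour Agilent mouse whole-genome expression arrays, 1 per group. Per the labels, cells were transfected with the pcDNA3.1 plasmid, either empty or carrying MARVELD1, and stable lines were obtained under G418, a drug that kills cells without the plasmid's resistance gene. Also per the labels, total RNA was extracted with TRIzol, cleaned on RNeasy columns and labelled with Cy3. Both arrays lay on 1 slide, at positions 3 and 4, and were read in 1 scan, so slide and scan do not separate the groups. Groups were taken from the labels alone.

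The deposited scanner files give, per the file headers, the fluorescence intensity of each spot as read by Agilent Feature Extraction 9.5.3.1, a tool that the submitters' processing notes also name. The processed intensity is background-subtracted and detrended across the slide by that program, with a small surrogate value in place of very low readings, per the file headers. No scaling between arrays is part of it. The authors also deposited a table of normalized intensity for 26851 probes. Each of its columns equals the processed intensity divided by 1 factor, 124.6 for the empty vector array and 123.3 for the array labelled MARVELD1, with 99.6% of probes within 1% of that factor. The column medians are 3.11 and 2.94, and 26799 of its probes were well above background on both arrays here. Flags for spots well above background, saturated spots and outliers were used as deposited. Later steps of the authors' processing are not given in the sources used here. Probe coordinates are those of the files, on mouse build mm9. No annotation of that build was used here, so whether a probe lies in an exon or an untranslated region is not known.

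Each array had 43379 non-control spots for 41174 distinct probes, of which 245 were printed 10 times. Outlier spots, 116 on the empty vector array and 223 on the other, were left out, and no spot was saturated (0 on each array). The log2 of the processed intensity minus the 75th percentile of its array was averaged over the spots of a probe. Probes were named through a RefSeq gene table of assembly GRCm38.p6, used for names and gene spans only. Of the 41084 probes with usable spots on both arrays, 24802 matched by accession, 6030 by symbol and 1808 by a unique older name, and 8444 stayed unnamed. A gene was represented by its probe with the highest mean over both arrays. Of 19698 named genes, 16532 had a probe well above background on at least 1 array and were kept. The limit to names found in that table was set after the files had been looked at.

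Where a probe was not well above background on 1 array, only a bound is given, as "at least N-fold". It sets the bright array's value against the higher of the dim probe's own value and the lowest value among well-measured probes on the dim array. That lowest intensity was 36.5 on the empty vector array and 36 on the other.

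With 1 array per group there are no replicates, so no test, p-value or standard error between groups is given, and the 2-fold limit is a limit of size. The spread of repeated spots and of different probes of a gene is technical only. For 47 gene lists, the median log2 difference of the detected members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called outside when its median lay beyond the central 95% of them. This describes these 2 arrays and does not test the conditions.

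The grouping, the main setting, the lists, the alternatives not marked below as added later and the rule for named genes were fixed before the data were examined. The rule takes Marveld1 and Itgb1. It also takes the 15 genes with the largest difference in each direction that were measured on both arrays and whose probes measured on both all differ the same way. Further, it takes the 8 largest bounds in each direction, and from each list the 2 highest and 2 lowest members and any other past 2-fold. Predicted and clone-named genes were left out of the parts on largest differences and bounds. From the resulting 268 genes, those described are a selection made after their values were seen. 1 gene that the rule selects is not reported here.

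The alternatives were scaling to the array median, quantile normalization, loess on mean intensity, normexp background correction (offset 50) with quantile normalization, no filter on dim probes, a filter on both arrays, the mean of all probes, the authors' processed values, and thresholds of 1.5-fold and 3-fold. Counting only genes with every probe past 2-fold, random lists matched on gene span too, and gene lists by the most 3-prime probe of each gene were added after seeing the data. Values under the alternatives are given relative to matched random lists, a measure chosen after the main list values had been seen. The bands within which an alternative counts as unmoved were also chosen then. They are 1 SD of the random medians for a list, 0.31 for a single probe, which is the SD of a difference between single spots, and 10% for the spread.

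Fold calls and list placement were tested on simulated data, with the spot noise of these arrays and 200 genes of the MARVELD1 against empty vector comparison given known fold changes among 16791 genes. Of the genes simulated at 4-fold and measured on both arrays, all 45 of 45 passed the 2-fold limit, as did 40 of 40 at 8-fold and 19 of 45 at exactly 2-fold. Of those not well above background on 1 array, for which only a bound is given, 5 of 5 passed at 4-fold, 7 of 9 at 8-fold and 4 of 5 at 2-fold. Spot noise alone carried 15 unchanged genes past the limit. With the real spread over 16532 genes, 8 of 100 null lists of 20 genes lay outside the central 95%, and 65 of 100 lay below it once their members were lowered by 0.3 log2. The loess step, the placement of neighbouring spots and the windows of neighbouring genes were also run on simulated data with a planted effect, and each recovered it. Quantile normalization, normexp and the choice of 3-prime probes were not simulated. R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, was used, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Probes without a name in the table were left out of the gene counts and are described separately.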

Results

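Gene expression was compared between NIH3T3 mouse fibroblasts stably carrying MARVELD1 on a plasmid and cells carrying the empty plasmid, with 1 array for each, to ask how MARVELD1 influences their expression profile. MARVELD1 is a small membrane protein with a MARVEL domain. On the empty vector array 68.7% of the spots were well above background, and on the array labelled MARVELD1 69.0%, with median intensities of 127.6 and 125.8 and 75th percentiles of 768.1 and 703.3. The number of arrays, 1 per group, limits the precision of everything that follows.

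Marveld1 itself was not higher on the array labelled MARVELD1. Its brighter probe, A_52_P541175 (mm9 chromosome 19, 42225823 to 42225882), read 8724.7 on the empty vector array and 6292.8 on the other, a log2 difference of -0.34, or 1.27-fold higher on the empty vector array. Its dimmer probe, A_51_P158814 (chromosome 19, 42224196 to 42224255), read 184.4 and 126.4, a log2 difference of -0.42, or 1.34-fold. The species and extent of the plasmid's insert are not given in the sources used here, so whether the probes read the insert is not known, and probes outside it would check nothing. As measured, the gene gives the label no support. Each probe is a single spot, and both differences are small beside the SD of 0.54 between different probes of a gene. They are near the SD of 0.31 of a difference between single spots, but that SD is pooled over bright and dim probes. Spots of some bright probes varied less, with SDs of 0.09 on the empty vector array and 0.11 on the other for Fn1. For Kitl these SDs were 0.15 and 0.18. Spot noise alone may therefore not account for the brighter probe. Because it is not known whether the probes read the insert, the differences do not speak clearly against the label either. Every direction below is that of the array labelled MARVELD1 relative to the empty vector array, resting on that label.

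Lists of extracellular matrix and fibroblast marker genes had lower medians on the array labelled MARVELD1 than random lists of matched signal, although most of their members differed by less than 2-fold. Single genes with large differences came from these and from other lists. Dlk1, an imprinted inhibitor of adipocyte differentiation, was 38.7-fold lower, at 121.8 against 5154.3, and its other probe gave a log2 difference of -5.33. Timp3, a matrix-bound metalloproteinase inhibitor, was 24.7-fold lower, the elastic fibre protein gene Fbln5 8.23-fold and the smooth muscle and fibroblast actin-binding gene Tagln 9.70-fold, with a bound of -3.73 from its other probe. Mmp3, the stromelysin that degrades matrix proteins, was 7.02-fold higher, and Mmp10 was 4.16-fold higher. They were the only 2 of 16 detected Mmp genes past 2-fold higher, and 0 were past 2-fold lower. The median of these 16, a set formed after the result was seen, lay at -0.33 relative to random lists. Among 16532 genes, 891 were at least 2-fold higher and 584 at least 2-fold lower, and 26 and 50 passed 8-fold. The majority depends on scaling: 653 were higher and 723 lower with scaling to the array median, 666 and 704 with quantile normalization, and 599 and 774 after loess. Normexp background correction with quantile normalization gave 307 and 421, and the values of the authors' deposited table gave 479 and 617. The median difference of all genes was 0.19 with the 75th percentile, 0.08 with the median, 0.08 with quantile normalization and 0.04 after loess, so gene lists are reported relative to random lists of matched signal.

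**Figure D1:**
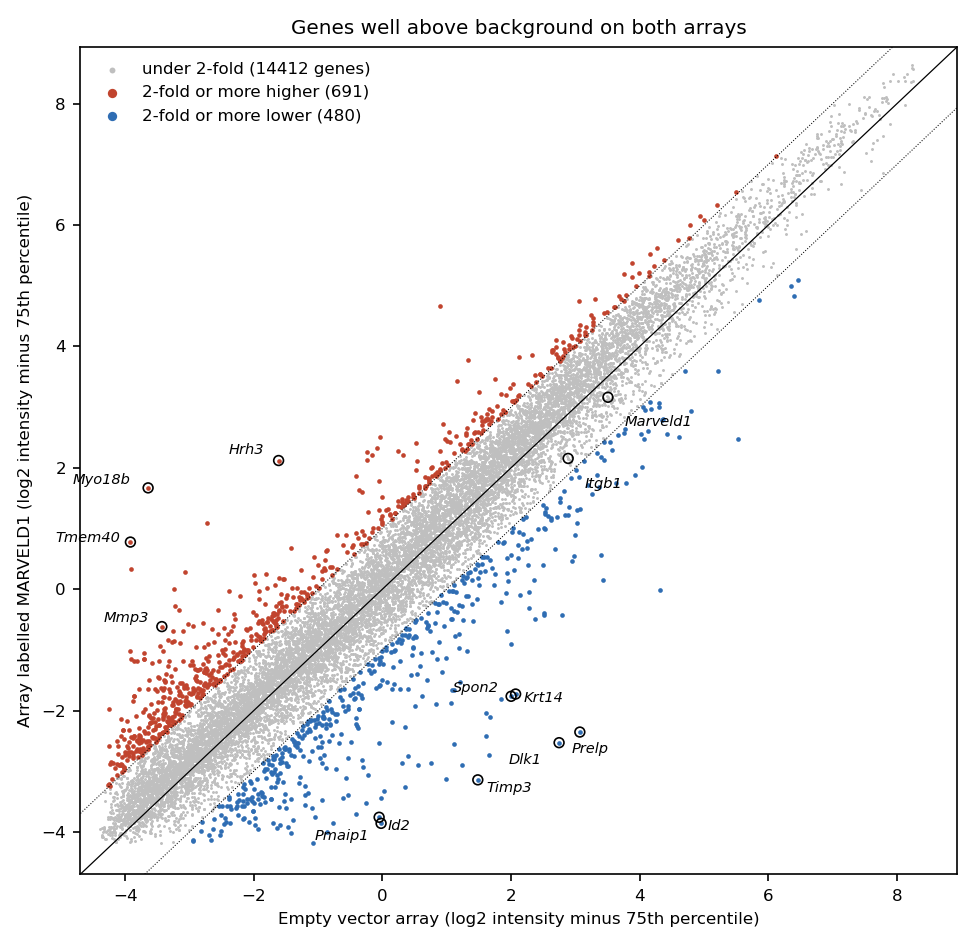
Log2 intensity minus the array's 75th percentile for the 15583 genes well above background on both arrays, empty vector on the horizontal axis and the array labelled MARVELD1 on the vertical axis, 1 point per gene. The solid line marks equality and the dotted lines 2-fold; 691 genes lie 2-fold or more above and 480 below, while the split over all genes turns with other scalings, with Prelp, Dlk1 and Timp3 far below and Myo18b and Tmem40 far above.

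Across the 15583 genes measured on both arrays, the log2 values correlated with a Pearson r of 0.974, across genes, which are not independent replicates. The log2 differences had an SD of 0.59 and an interquartile range of 0.61. Repeated spots of a probe had an SD of 0.24 on the empty vector array and 0.19 on the other, so a difference between single spots had a technical SD of 0.31. Different probes of a gene differed more, with an SD of 0.54 over 5486 genes.

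Itgb1, the beta-1 integrin subunit that binds collagen and fibronectin, was lower on the array labelled MARVELD1. Its probe with 10 spots per array (A_51_P286527, mm9 chromosome 8, 131256492 to 131256551) read 5682.5 and 3129.6, a log2 difference of -0.73 with a standard error of 0.031 over spots, which covers spot noise only. A second probe (A_52_P351816, 131246349 to 131246408) gave -1.80, and the remaining probe was not well above background on either array. Of 17 detected integrin genes, 5 were 2-fold or more higher and 1 lower, and the list lay inside the range of random lists, but below it (-0.29) with the most 3-prime probe of each gene. Itgb7 was 3.23-fold higher. Itgb4, the beta-4 subunit of hemidesmosomes, was 9.28-fold lower by its brightest probe and -3.42 by another, while a dim probe gave 1.59 in the opposite direction.

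Collagens stood furthest from random lists. The list of fibrillar and basement membrane collagens, which also holds Col6a1, Col6a2 and Col12a1, had 16 detected genes. Of these, 7 were at least 2-fold lower and 0 higher, with a median of -0.66, or -0.92 relative to random lists of matched signal. A set formed after the result was seen took all 37 detected genes whose names begin with Col and a number. Of them 8 were lower and 3 higher past 2-fold, with a relative median of -0.52. Col6a1 and Col6a2, whose chains assemble into the same microfibrils, were 3.21-fold and 3.83-fold lower, the latter with another probe just under 2-fold lower, Col5a2 2.95-fold and Col3a1 2.94-fold, although another probe of Col3a1 gave -0.10. Col12a1 was at least 28.9-fold lower, with a second probe lower as well, by a bound of -0.98. Col5a3 and Col18a1 were 1.95-fold and 1.46-fold higher. Among 36 other extracellular matrix genes, 5 were 2-fold or more lower and 3 higher, with a relative median of -0.46. Fibrillin-1 (Fbn1) was 2.49-fold lower and fibronectin (Fn1) 2.18-fold, with further probes of -2.13 and -2.47 and a bound of -0.08 from another Fn1 probe. Mfap4 was at least 2.78-fold higher, and Postn was 2.76-fold higher by its brightest probe and -0.20 by another.

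**Figure D2:**
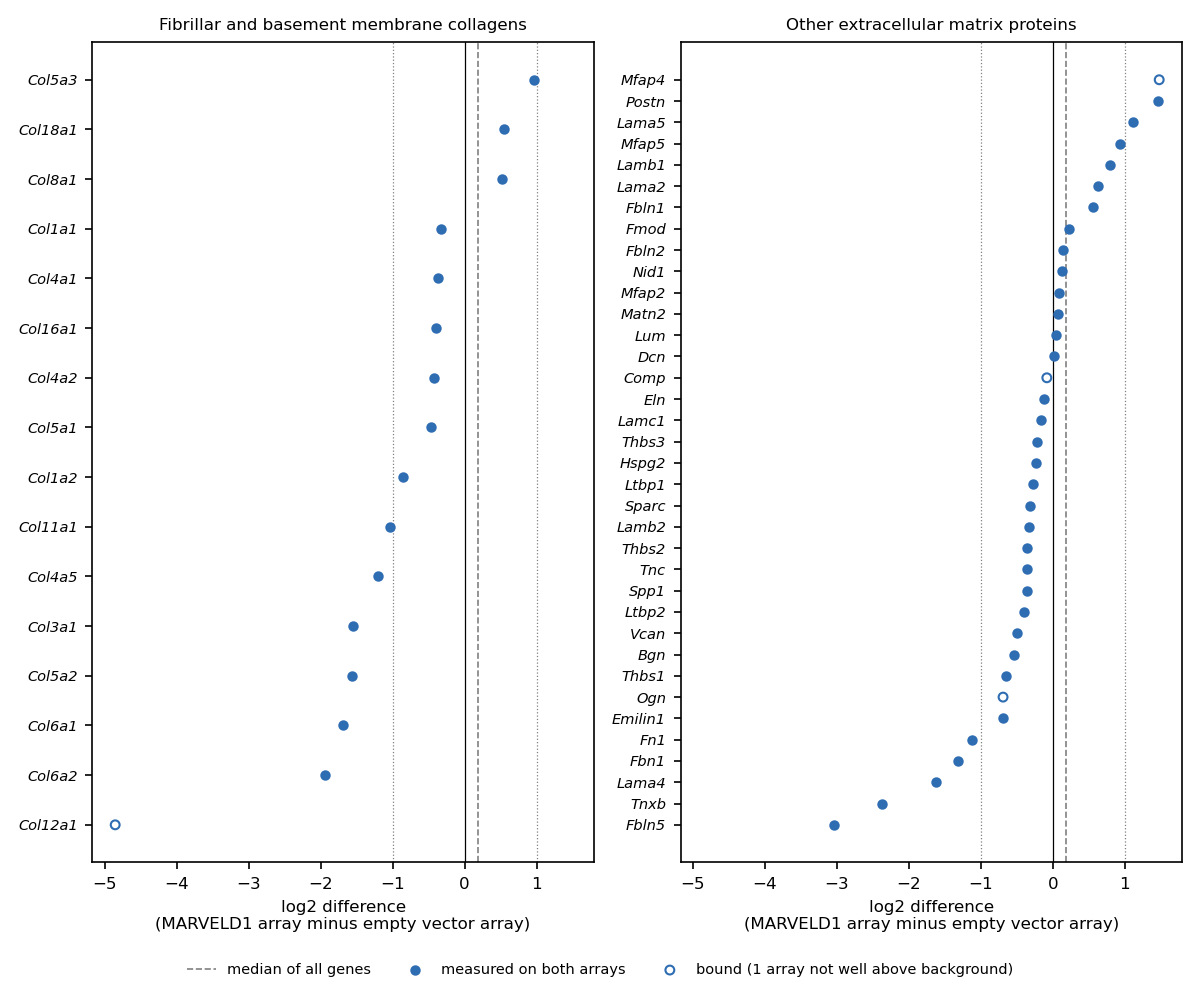
Log2 difference (array labelled MARVELD1 minus empty vector) of the detected genes of 2 lists, 1 point per gene by its brightest probe, with open points for bounds. The list of fibrillar and basement membrane collagens is on the left and that of other extracellular matrix proteins on the right. Collagen genes outside the list are not shown. The dashed line is the median of all genes (0.19) and the dotted lines mark 2-fold. Of the listed genes, 13 of 16 collagens and 22 of 36 other matrix genes lie below 0.

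Fibroblast markers and matrix enzymes differed in the same sense as lists. Of 23 mesenchymal and fibroblast markers, 5 were 2-fold or more lower and 0 higher, with a relative median of -0.61. Mgp, an inhibitor of calcification, was lower by a log2 difference of -2.58, the PDGF receptor gene Pdgfrb was 4.30-fold lower and the surface antigen gene Ly6a 3.64-fold. Of 26 matrix proteases and inhibitors, 5 were higher and 2 lower past 2-fold, yet the median lay at -0.48 relative to random lists, with 14 of the 26 lower. It was -0.23 without the filter on dim probes and -0.29 with normexp. Plau and its receptor gene Plaur, which act in plasminogen activation, were 2.06-fold and 2.79-fold higher, with other probes under 2-fold, at 0.82 for Plau and 0.69 for Plaur. Growth factors and receptor tyrosine kinases, 47 genes, had 9 lower and 2 higher, with a relative median of -0.27; Fgfr1 was 3.16-fold lower, and its other probes gave -1.73, -2.18 and -0.96. Hbegf, an EGF receptor ligand, was 3.71-fold higher.

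Interferon and antigen presentation lists lay below the random range too. Of 41 interferon stimulated genes, 5 were 2-fold or more lower and 0 higher, with a relative median of -0.43. Ifit1 was 4.56-fold lower, the ubiquitin-like modifier gene Isg15 3.52-fold and Ifit3 3.05-fold. None of 18 genes for MHC class I and antigen presentation passed 2-fold (0 higher, 0 lower), but 14 were lower and the relative median was -0.40. Tap1, a subunit of the peptide transporter, was 1.95-fold lower. Among 24 chemokines and cytokines, 2 were higher and 2 lower, with a relative median of -0.27. The chemokine list was inside the range of random lists with quantile normalization, after loess, with normexp and without the filter on dim probes. Ccl7, a monocyte attractant, was 2.97-fold lower, and its other probe gave -1.54.

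Lists of NRF2 targets, the unfolded protein response, p53 targets and G1 regulators were also below the random range. NRF2 targets and glutathione genes had 7 of 36 members lower and 0 higher past 2-fold, with a relative median of -0.30. Mgst1 was 6.03-fold lower with its other probe at -2.63, catalase (Cat) 3.38-fold and the quinone reductase gene Nqo1 2.82-fold. In the unfolded protein response list 4 of 30 genes were lower and 0 higher, with a relative median of -0.37. Sdf2l1, an endoplasmic reticulum protein gene, was 12.6-fold lower and the disulfide isomerase gene Pdia4 5.05-fold. Among 25 p53 targets 3 were lower and 0 higher, with a relative median of -0.32. Pmaip1, which encodes the pro-apoptotic BH3-only protein Noxa, was 14.3-fold lower, and the growth arrest gene Gadd45a was 3.81-fold lower. Of 17 cyclin dependent kinase inhibitors and G1 regulators, 1 was 2-fold or more lower and 0 higher, with a relative median of -0.40, and the growth arrest gene Gas1 was 7.49-fold lower.

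The remaining lists below the random range had few members past 2-fold. Cholesterol synthesis (26 genes) had a relative median of -0.29. There Insig1, which retains the sterol sensor in the endoplasmic reticulum, was 13.6-fold lower by its brightest probe, while its other probe gave 0.04. Histone genes (28) had a relative median of -0.24 and were inside the random range without the filter (-0.19). Lysosome and autophagy genes (32) were at -0.19 and inside with the filter on both arrays (-0.19), with the mean of all probes (-0.18) and in the authors' table (-0.19). Bone and cartilage markers (15) were at -0.36, but at -0.19 and inside with the mean of all probes; 2 were higher and 1 lower past 2-fold, with Bglap, the osteocalcin gene, 2.29-fold lower and Phex 2.30-fold higher. In all, 16 of the 47 lists lay outside the central 95% of random lists, all 16 below it and 0 above. By chance 2.4 would be expected for independent lists of unrelated genes. Of simulated null lists, however, 8 of 100 lay outside. Random lists also do not reproduce members of a list that vary together, so the number expected for real lists may be higher than 2.4. Some lists share members. Over 4606 genes with probes measured on both arrays and 500 bases or more apart, the log2 difference of the most 5-prime probe minus that of the most 3-prime probe had a median of -0.28, with an interquartile range of -0.69 to 0.14. With the most 3-prime probe of each gene, all 16 of these lists stayed outside, and 4 others were newly outside: integrins, the MARVEL domain family and TGF-beta genes below and the respiratory chain above.

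**Figure D3:**
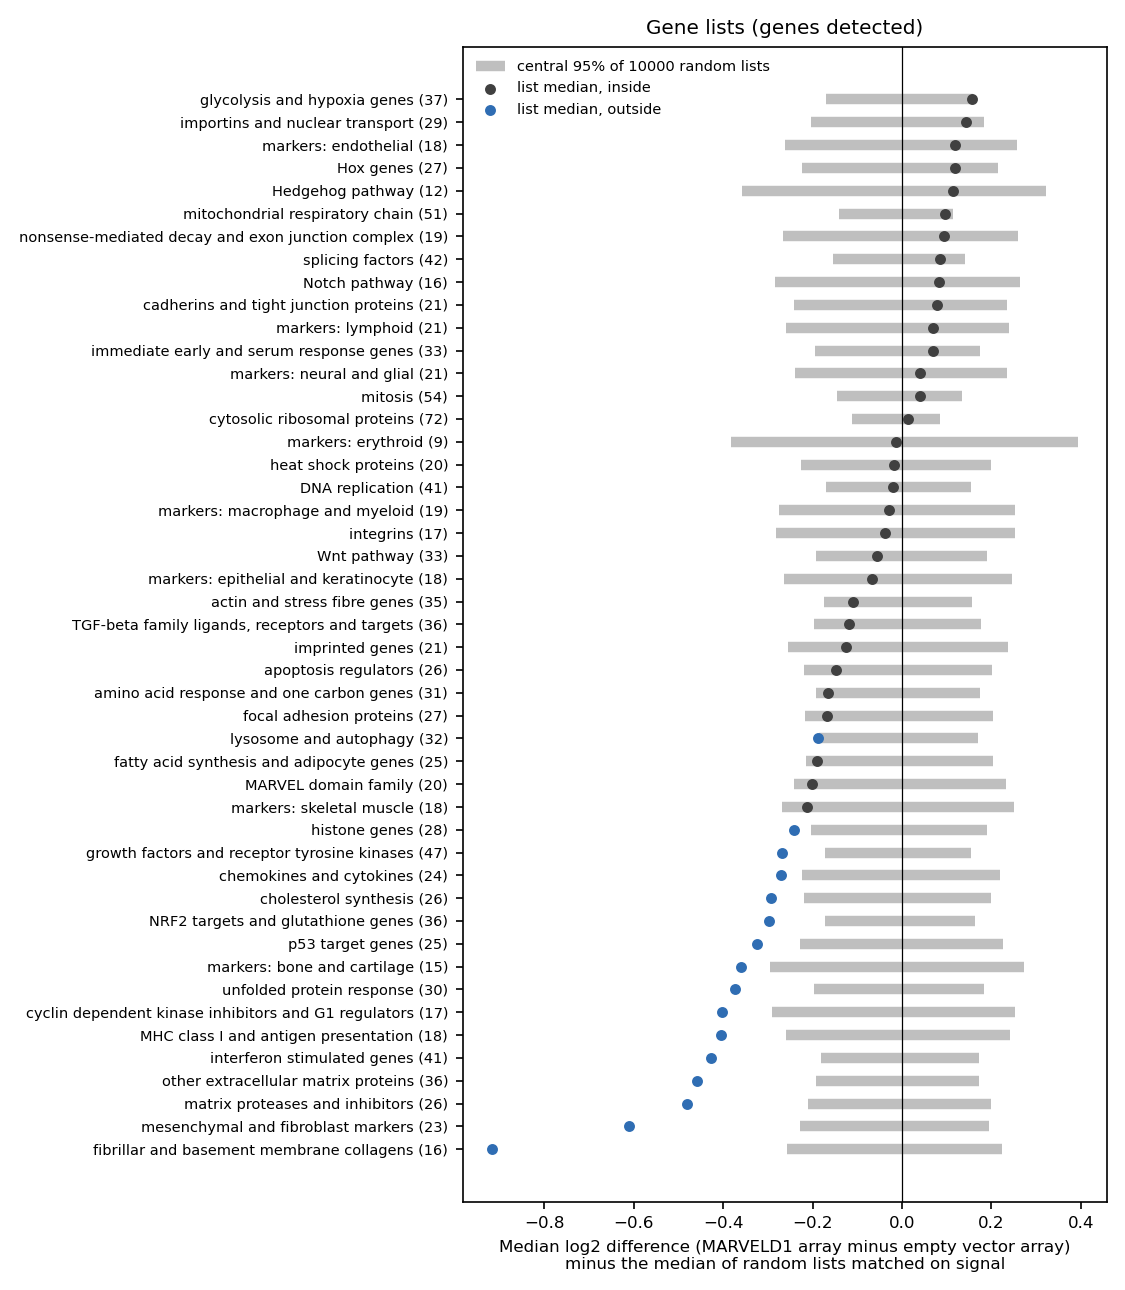
Median log2 difference of each of the 47 lists minus the median of its matched random lists, with the number of detected genes in parentheses; grey bars span the central 95% of 10000 random lists. The 16 lists outside it (blue) all lie below, from -0.19 for lysosome and autophagy genes to -0.92 for collagens.

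Proliferation, translation and RNA processing lists were inside the random range in the main setting. DNA replication (41 genes, relative median -0.02) had 1 gene past 2-fold, Ccne2, encoding cyclin E2, at 2.56-fold lower with its other probe at -1.41. Mitosis genes (54) were at 0.04, with 1 higher and 1 lower past 2-fold: Bub1 2.18-fold higher by 1 probe and 0.10 by the other, and Hmmr 2.05-fold lower. None of 72 cytosolic ribosomal protein genes (relative median 0.01) and none of 51 respiratory chain genes (0.10) passed 2-fold, 0 in either direction. The respiratory chain list lay above the range with the mean of all probes (0.12) and with 3-prime probes (0.12). Splicing factors (42) were at 0.08, importins and nuclear transport (29) at 0.14, and nonsense-mediated decay and exon junction genes (19) at 0.09. Glycolysis and hypoxia genes (37) came closest to the upper limit, at percentile 97.3 with a relative median of 0.16, and were above it with the mean of all probes (0.17) and in the authors' table (0.16). Of them 3 were higher and 1 lower past 2-fold. Pdk1, which inhibits pyruvate dehydrogenase, was 2.56-fold higher with its other probe at 1.25, and Hk2 was 2.06-fold higher, whereas Eno1 was 4.09-fold lower.

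Adhesion and cytoskeleton lists were inside in the main setting, though not under every alternative. Of 27 focal adhesion genes 2 were lower and 0 higher (relative median -0.17), with Actn1, encoding alpha-actinin, 2.36-fold lower. This list lay below the random range with quantile normalization (-0.31), after loess (-0.27), with normexp (-0.24) and with the mean of all probes (-0.31). Of 35 actin and stress fibre genes 4 were lower and 0 higher (-0.11, but -0.36 and below the range with the mean of all probes). Cadherins and tight junction genes (21) were at 0.08, with 1 higher and 2 lower past 2-fold, among them the N-cadherin gene Cdh2 6.52-fold lower by the only probe measured on both arrays and a bound of 0.64 in the opposite direction from a dim one. The MARVEL domain family (20 genes) was at -0.20, or -0.30 and below the range with 3-prime probes, with 2 members higher and 1 lower, Myadm at 3.30-fold, whose other probe gave a bound of -0.06. Hox genes (27) had 5 members higher and 0 lower with a relative median of 0.12; Hoxd11 was 7.67-fold, Hoxd12 2.98-fold and Hoxd13 at least 2.30-fold higher, and for Hoxb8, at least 2.73-fold higher, the other probe gave -0.20. TGF-beta genes (36) were at -0.12, but below the range with the mean of all probes (-0.20) and with 3-prime probes (-0.31). Of them 3 were lower and 1 higher past 2-fold, with Id2 13.1-fold lower by its brightest probe and -1.92 by the other, and Id3 2.21-fold lower. The Wnt list (33) was at -0.06 with 2 higher and 2 lower, among them Ccn5 12.7-fold lower and Wnt5b at least 6.15-fold higher, with a bound of 0.84 from its other probe. Imprinted genes (21) were at -0.12 and immediate early genes (33) at 0.07, the latter with 3 lower and 1 higher past 2-fold and Fos 2.51-fold lower.

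Markers of other cell types, apart from bone and cartilage, were inside the random range. Some of them read near the lowest well-measured intensities, 36.5 on the empty vector array and 36 on the other. Cd3d read 47 and 33.2 on these arrays, and Cd4 50.3 and 76. How many members read so low was not counted, so a detected marker need not be expressed. Relative medians were -0.21 for skeletal muscle (18 genes), -0.07 for epithelial and keratinocyte (18), 0.12 for endothelial (18), -0.03 for macrophage and myeloid (19), 0.07 for lymphoid (21), 0.04 for neural and glial (21) and -0.01 for erythroid (9). Krt14, a basal keratinocyte keratin gene, was 13.9-fold lower and read 3226.6 on the empty vector array, the only 1 of the epithelial and keratinocyte list lower past 2-fold, while 2 were higher, Krt5 at 2.02-fold and Krt18 at least 2.35-fold. The other lists inside were Notch (0.08), Hedgehog (0.11), fatty acid and adipocyte genes (-0.19), apoptosis regulators (-0.15), amino acid response genes (-0.17) and heat shock proteins (-0.02). Of these, fatty acid genes lay below the range with normexp (-0.22), and amino acid response genes with normexp (-0.19) and with the mean of all probes (-0.20). Fabp4, the adipocyte fatty acid binding protein gene, was 3.79-fold lower, and its other probes gave -2.02 and -2.28.

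Of the largest differences measured on both arrays, Prelp, a matrix proteoglycan gene, was 42.9-fold lower, but its other probe gave only -0.29. Esx1 was 20.8-fold lower, Slurp1 17.5-fold and Spon2 13.6-fold, the last with a second probe at -2.75. Arf5 was 17.6-fold lower by a single probe. The clathrin heavy chain gene Cltc was 12.5-fold lower with other probes at -2.30 and -0.27, and the importin gene Tnpo2 12.2-fold lower with another at -0.14. In the other direction Myo18b, an unconventional myosin gene, was 39.7-fold higher, with a bound of 1.75 from its other probe. Tmem40 was 25.9-fold higher with its other probe at 2.56, and Pla2g5, Hrh3 and Prkcb were 14.1-fold, 13.3-fold and 10.3-fold higher, each by a single detected probe. Park7 was 13.8-fold higher by a single probe whose spot lies beside another with a difference past 8-fold.

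Of genes not well above background on the empty vector array, Lcn2, encoding the iron-siderophore binding protein lipocalin-2, was at least 27.6-fold higher, Sorbs2 at least 15.4-fold and Podxl at least 14.3-fold. Among genes not well above background on the array labelled MARVELD1, Cluh, Metrnl and Tsen15 were at least 265-fold, 263-fold and 155-fold lower. Each rests on a single spot that read 10410.4, 10335.4 and 6094.3 on the empty vector array and 11.9, 7.6 and 9.0 on the other, and the second probe of Metrnl gave a bound of only -0.66. In all, 551 genes were well above background only on the array labelled MARVELD1 and 398 only on the empty vector array. Of the 176 genes past 2-fold that the naming rule selects, 61 had another detected probe. Every other probe passed 2-fold in the same direction for 14 of them, at least 1 other probe was under 2-fold in the same direction for 28, and at least 1 lay in the opposite direction for 19.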

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

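The test of single-spot failure by second probes, the tests on Marveld1 and the one on culture or clone differences were chosen only after the result was seen; the collagen and matrix pattern was itself picked from the list values. Probes without a gene name stand outside the gene comparisons, and some carried signal on 1 array that was not well above background on the other. A_51_P110421 (mm9 chromosome 5, 3473216 to 3473275) was at least 16.4-fold higher on the array labelled MARVELD1, A_52_P1180111 (chromosome 10, 122858415 to 122858474) at least 16.01-fold and A_52_P670484 (chromosome 1, 106853667 to 106853726) at least 10.8-fold. In the other direction A_52_P656096 (chromosome 14, 69964826 to 69964885) was at least 23.7-fold lower and A_52_P577438 (chromosome 4, 34539778 to 34539837) at least 15.6-fold, but their spots lie next to each other. A_52_P885214 (chromosome 11, 53330578 to 53330637) was at least 7.82-fold lower. In all, 409 unnamed probes were well above background only on the array labelled MARVELD1 and 288 only on the empty vector array. Past 2-fold 413 were higher and 138 lower with the 75th percentile, a scaling under which genes also had more higher than lower, and other scalings were not run for these probes.

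The first pattern weighed is the set of differences of 8-fold or more. Of 126 single spots with such a difference, 13.5% lay next to another, against at most 8.73% in 1000 random placements, so local surface defects are a candidate explanation for those 17 spots, which include the spots of Park7, Itpkc and Ano4. The other spots had no such neighbour. Among genes past 8-fold with a second detected probe, 44% of the second probes (11 of 25) differed by 2-fold or more in the same direction, between the limits set for failed spots and for real differences, so single-spot failure may account for part of the pattern. Of 175 probes with 10 spots, 1 (0.57%) differed by 4-fold or more, against 0.75% of single-spot probes of matched signal, which meets neither limit set for noise, while at 2-fold 9.14% of them (16) differed against 7.35%, against single-spot noise at that size.

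The second pattern is the lower level of collagen and matrix genes, 52 genes with a median -0.58 relative to random lists, whose central range began at -0.15. After loess the shift was -0.66. This step cannot decide on a dependence on signal, because the random lists were already matched on mean signal and loess moves both alike. With only the most 3-prime probe of each gene the shift was -0.58, but a gene with a single detected probe keeps its value there. Only 15 of the 52 genes had 2 probes measured on both arrays and 500 bases or more apart. In those 15 the 5-prime probe lay at a median of 0.35 relative to the 3-prime one, opposite in sign to a loss of the 5-prime part of transcripts. Over 4606 genes that median was -0.28. The pattern was picked by the brightest probe of each gene, and a dimmer probe can differ by another amount. The dimmer probe gave a smaller difference for Col3a1 and a larger one for Fn1. The 0.35 therefore cannot decide for these 15 genes, nor can the test for the other matrix genes. Relative to random lists matched on gene span the shift was -0.57, against a lower level of long genes as a class. With 1 pair of lines on the arrays, culture or clone differences other than MARVELD1 stay open and cannot be told apart from it. A biological effect of MARVELD1 is thus only an untested possibility here.

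The third pattern is Marveld1, lower on the array labelled MARVELD1 by both probes. The brighter probe gave -0.34 and the dimmer -0.42, neither near 2-fold in either direction. Probes outside the plasmid's insert may give such values, as may a line that does not express the insert. An exchange of the arrays would put the plasmid's transcript on the array labelled empty vector, and it cannot be told apart from the labelled order because whether the probes read the insert is not known.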

How the results depend on the processing

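The count of genes with every probe past 2-fold, the random lists matched on gene span and the lists by the most 3-prime probe were tests chosen only after the result was seen, as was the relative list measure. Of 1338 values of the 176 genes past 2-fold under 8 alternatives, 1334 kept their direction and 1208 stayed past 2-fold. The 4 that changed direction were Srsf1 at -0.36 and H1f0 at -0.33 with the mean of all probes, and Hoxb8 at -0.20 with the filter on both arrays and -0.31 in the authors' table. These counts are no independent check, because every alternative reuses the same spots. Scaling to the array median and dropping the filter left all 268 named genes unmoved. With normexp, 110 of the 268 moved by 0.31 or more. Higher genes numbered 307 with normexp, 479 in the authors' table (617 lower there), 3210 at 1.5-fold and 200 at 3-fold, and lower genes 1482 and 216 at those thresholds, as a lower or higher limit must give. Of genes with several probes, 25 of 203 higher and 43 of 143 lower passed 2-fold with every probe. The SD between arrays was 0.49 with normexp. The 16 lists stayed outside random lists 14 to 16 at a time. Not all settings are separate checks of this. Scaling to the array median moves a list and its random lists alike, and loess nearly so. The authors' table differs from the processed intensity by 1 factor per array, so it nearly repeats the filter on both arrays. Up to 6 other lists were newly outside, with the mean of all probes, and each is named in the report. With 3-prime probes collagens were at -1.05, growth factors at -0.42 and the unfolded protein response at -0.25. Relative medians that moved were, for matrix proteases, -0.35 with quantile normalization, -0.35 with loess, -0.29 with normexp and -0.23 without a filter; for chemokines, then inside the random range, -0.14 with quantile normalization, -0.17 with loess, -0.10 with normexp and -0.048 without a filter. With normexp interferon genes were at -0.30, lysosome genes at -0.28 and bone markers at -0.21. Without a filter collagens were at -0.63 and fibroblast markers at -0.46. With the filter on both arrays collagens were at -0.72, as in the authors' table (-0.72). With the mean of all probes collagens were at -1.05, other matrix genes at -0.34, interferon genes at -0.58, the unfolded protein response at -0.51, NRF2 targets at -0.39 and bone markers, then inside, at -0.19. Apart from the choice of genes and thresholds, the cause was not tested. Both Marveld1 probes stayed below 0 under every alternative. No paired analysis was possible because each group has 1 array. Signal over background limits 551 and 398 genes to bounds.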

Other observations

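The scan of gene families by name was chosen after the result was seen, while the tests of neighbouring genes were written down before their values were computed. Families were formed by the letters that begin a gene's name, and 258 had at least 8 detected genes. Of these, 31 had a median outside the central 95% of 2000 random lists. By chance 5% would be outside if members were unrelated, and more if members of a family vary together. Among families above random lists of matched signal were DEAD-box helicase genes (Ddx, 32 genes) by 0.26, RNA-binding motif genes (Rbm, 33) by 0.28, translation initiation factors (Eif, 51) by 0.16, mitochondrial ribosomal proteins (Mrpl, 49) by 0.16 and nucleoporins (Nup, 19) by 0.31. Casein kinase genes (Csnk, 9) lay 0.44 above, the olfactory receptor genes (Olfr, 755), the largest family scanned, 0.10 above and vomeronasal receptor genes (Vmn, 98) 0.17 above. Past 2-fold, 87 Olfr genes were higher and 7 lower, and 14 Vmn genes were higher and 1 lower. How near to background these receptor genes read, and whether their probes share sequence, was not examined, so their shift may not reflect expression. Families inside the range included Dhx helicases (16 genes, 0.004), Srsf splicing factors (11, 0.19), Rpl (49, 0.06) and Mrps ribosomal proteins (29, 0.07). Collagen genes (Col, 37) lay at -0.52, aldehyde dehydrogenases (Aldh, 20) at -0.44, Sox factors (15) at -0.38, matrix metalloproteinases (Mmp, 16) at -0.33 and Klf factors (17) at -0.32.

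A hypothesis of its own is that the lines differ in copy number of some chromosome segments. Along each chromosome the median difference of every 50 neighbouring genes was set against 1000 shuffles of gene order over 16479 genes. The largest shift was -0.50 on chromosome 13 (mm9 41196796 to 51247714), past the largest of the shuffles at 0.45 in size, and a window on chromosome X (69068199 to 71655008) at 0.48 was also past it. A window on chromosome 4 (106873130 to 115005402) at -0.40 was matched or exceeded by 18 shuffles. With 1 gene per name stem the chromosome 13 window kept a shift of -0.47, so clusters of related genes sharing sequence are unlikely as its cause. By whole chromosome the median lay -0.24 from that of all genes on chromosome 4 and -0.19 on chromosome 13. Segments of different copy number are consistent with these values, as are shared regulation of neighbours, which was not tested, and the arrays do not show which line differs from the parental cells.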
